A study of Mus musculus with 11 samples.

How the data were processed

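Kidney RNA from 11 female mice was profiled on Illumina mouse bead arrays, 1 array per mouse: 4 mice with an intact Cldn16 gene (WT), 3 heterozygotes (Het) and 4 homozygotes for the targeted allele (KO). Per the labels, the mice were 8 weeks old, at postnatal day 58 (7 mice) or 59 (4 mice, of which 2 WT, 1 Het and 1 KO), and came from a mixed 129S7/SvEvBrd-Hprtb-m2 and C57BL/6N background. Per the labels' protocols, the kidneys were frozen without their poles. Their RNA was isolated in Trizol, treated with DNase and cleaned on columns, and it was amplified to biotinylated cRNA with the Illumina TotalPrep kit. Groups were taken from the genotype in the labels, where each sample is listed as 1 numbered mouse. Replicate numbers within a group name a sample and pair nothing. The arrays lay on 2 slides, as the array positions in the labels show: slide 1 held 2 WT, 2 Het and 2 KO, and slide 2 held 2 WT, 1 Het and 2 KO.

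The authors deposited, per the file headers, a linear intensity (average bead signal) and a detection p-value for each of 45281 probes on each array. The submitters' processing notes name BeadStudio, with no version; the background treatment and the exact definition of the detection p-value are not given in the sources used here. The deposited intensities were not normalized between arrays, since their medians ran from 70.3 to 76.6, and none lay below 40.3. A second deposited table holds the authors' processed intensities on a linear scale. Its array medians were 73.6 or 73.7, each array ranked its probes as in the unnormalized table (lowest rank correlation 1), and a quantile normalization of the unnormalized intensities came within a median of 0.00392 intensity units of it. Its scale and centring were thus found from the values, not from a stated method.

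The unnormalized intensities were background-corrected with limma's normexp method, in which the negative controls are inferred from the detection p-values, with an offset of 16, then quantile normalized and put on the log2 scale (limma 3.58.1 in R 4.3.3; statmod 1.5.0). Probes with a detection p under 0.05 on at least 3 arrays were tested, which left 22856. Precision is limited by the number of arrays, and between 41.6% and 43.6% of probes had a detection p under 0.01 on an array. Probes were named through the platform annotation: 34885 probes had 1 gene symbol, 18 had several and 10378 had none, and 34807 matched an Entrez identifier in a current gene table, which updated 0 symbols. Of the tested probes, 19265 had 1 symbol and 3591 had none or several; the latter appear under their probe identifiers. No genome build is named in the sources used here, so gene order was taken from a mouse reference table (assembly GRCm38.p6) only to find which genes neighbour Cldn16, and no coordinates are given.

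All 11 arrays entered 1 linear model with a mean per genotype (lmFit and eBayes, prior degrees of freedom 5.19), from which KO vs WT, Het vs WT, KO vs Het and the departure of Het from the midpoint of WT and KO were taken. P-values are two-sided and adjusted by the Benjamini-Hochberg method over the tested probes, with a threshold of 0.05. Differences are log2 differences with the model's standard error (SE), so that 1 on this scale is a doubling; the offset makes changes of dim probes look smaller than they were. A group in which a probe had no array with a detection p under 0.01 is called below background. The fold is then a lower bound, taken between the mean of the brighter group and the mean, per array of the dimmer group, of the higher of the probe's own value and the lowest value among probes with a detection p under 0.01.

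Gene lists were tested with limma's camera (preset inter-gene correlation 0.01), 1 probe per gene (the brightest on average, 12179 genes), adjusted over the lists with at least 5 measured genes. There were 28 lists: nephron segments and cell types (proximal tubule, thin limb of Henle, thick ascending limb, distal convoluted tubule, collecting duct principal cell, intercalated cell, podocyte, endothelium, immune cells), transport and hormones (calcium and magnesium handling; vitamin D, PTH and phosphate; claudins and tight junctions; the renin-angiotensin-aldosterone system with sodium handling; water handling and osmotic response), responses (tubule injury, extracellular matrix, interferon response, immediate early and heat shock genes, circadian clock, fatty acid oxidation with PPAR alpha, cholesterol synthesis, cell cycle, oxidative stress), Cldn16 neighbours on chromosome 16, and tissues that a dissection could bring along (blood, adipose tissue, adrenal gland, muscle and ureter). Of 589 list entries, 55 matched no symbol of the array annotation. Blood (4 measured genes) and adrenal gland (3) were too small for camera, which left 26 lists tested. A list score is the mean over the list's genes of an array's log2 intensity minus the WT mean, compared by exact two-sided permutation tests, for which 4 against 4 arrays and 3 against 4 arrays both allow no p below 0.0286.

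The main tests, the lists, the rule for naming genes and most alternatives were chosen before the data were examined; what was chosen later is named as such where it is reported. Named are Cldn16; in each genotype comparison up to 15 called genes in each direction, or, with fewer than 5 called, the 5 genes with the smallest unadjusted p; for each list up to 4 members with the smallest p in KO vs WT; and any member of the calcium and magnesium list and the vitamin D list. A gene named outside this rule is marked as chosen after its values were seen. Alternatives covered background correction, normalization, the authors' values, the offset, the filter on dim probes, the slide, the postnatal day, array weights, the variance prior, the samples in the fit, the inter-gene correlation, the probe per gene, the distance from Cldn16 and the omission of each array.

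The model was tested on simulated data with 200 changed probes among 22856, in 10 runs. Each probe was drawn on its own with normal noise, so genes were uncorrelated and arrays had no structure in common. For KO vs WT it recovered 23.1% of log2 differences of 0.5, 92.7% of 1 and 100% of 2, with 5.77% of its calls false. For Het vs WT it recovered 16.1%, 91.9% and 99.7%, for KO vs Het 15.1%, 89.6% and 98.9%, and for the departure from the midpoint 28.5%, 94.3% and 99.7%. A list of 13 genes shifted by 0.3 was called in 10 of 10 runs for each genotype comparison, with 0 other lists called in KO vs WT, 2 of 250 in Het vs WT and 0 in KO vs Het. In the real data genes of several lists varied together (estimated correlation 0.15 for the distal convoluted tubule, 0.17 for the collecting duct). The simulated rates therefore hold only for independent probes and do not show how often lists are wrongly called in these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.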

Results

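Claudin-16 is a tight junction protein of the thick ascending limb of the kidney, where it forms part of the paracellular route by which magnesium and calcium are reabsorbed. Its loss in humans causes renal wasting of both ions. Kidneys of female mice with 2, 1 or no intact Cldn16 alleles were compared on bead arrays, with n = 4 WT, n = 3 Het and n = 4 KO mice. Between 18854 and 19742 probes per array had a detection p under 0.01, and pairwise correlations between arrays over all tested probes ran from 0.981 to 0.991. The 1st principal component held 20.1% of the variance and the 2nd 14.6%. KO 2 lay farthest out on the 1st (40.7) and WT 3 on the 2nd (-32.1).

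The targeted gene itself is represented by 1 probe (ILMN_2954714, chromosome 16), detected on all 11 arrays. Its log2 intensity was 9.50 ± 0.23 (SD, n = 4) in WT, 9.33 ± 0.06 (n = 3) in Het and 8.98 ± 0.33 (n = 4) in KO kidneys. The KO minus WT difference of -0.53 ± 0.16 (SE) did not pass the threshold in limma (adjusted p = 0.227) nor in the exact two-sided permutation test (p = 0.0571 over 70 arrangements). With the slide as a block the difference was -0.53 (adjusted p = 0.231 in limma), and within the slides it was -0.42 and -0.63. Over the alternatives fixed in advance it ranged from -0.64 to -0.36 (adjusted p from 0.177 to 0.898 in limma). With the omission of the 3 arrays with the most adipose signal, chosen after the data were seen, the range was -0.79 to -0.36 (adjusted p from 0.160 to 0.898). Het minus WT was -0.17 ± 0.17 (adjusted p = 0.902 in limma, exact permutation p = 0.257) and KO minus Het -0.36 ± 0.17 (adjusted p = 0.915 in limma, exact permutation p = 0.143). The position of the probe relative to the deleted part of the gene is not given in the sources used here, so its signal neither checks nor contradicts the genotype labels.

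**Figure D1:**
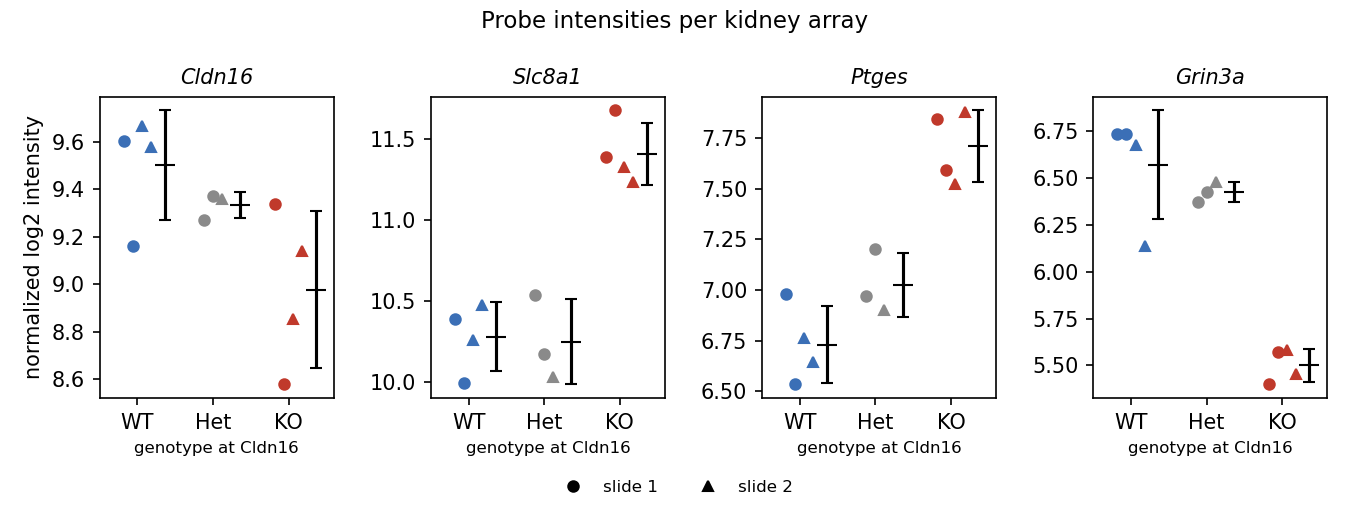
Normalized log2 intensity (vertical axis) of the probes for Cldn16, Slc8a1, Ptges and Grin3a in each kidney, by genotype (horizontal axis); circles are arrays of slide 1, triangles of slide 2, and the bars give the mean ± SD of each genotype. Slc8a1 averaged 10.28 in WT, 10.25 in Het and 11.40 in KO, with no overlap between WT and KO, whereas the WT and KO values of Cldn16 overlap.

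The comparison of KO with WT asks what the loss of both alleles changes in the kidney. Slc8a1, the sodium-calcium exchanger through which distal tubule cells return calcium to the blood, rose by 1.13 ± 0.15 log2 units (SE), or 2.18-fold, from 10.28 ± 0.21 (SD, n = 4) to 11.40 ± 0.19 (n = 4). Ptges, an enzyme that makes prostaglandin E, rose by 0.98 ± 0.13, from 6.73 ± 0.19 to 7.71 ± 0.18. Tnn, an extracellular matrix protein of the tenascin family, rose from below background in all 4 WT kidneys, at least 2.15-fold (fitted difference 1.45 ± 0.20). Antxr1, a cell surface receptor that binds collagen, rose by 0.74 ± 0.11. The NMDA receptor subunit Grin3a fell by 1.07 ± 0.13. The sperm tail protein gene Odf4 fell by 0.75 ± 0.11. Abhd10, which encodes a mitochondrial hydrolase and lies on chromosome 16, fell by 0.75 ± 0.11.

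Besides these, the X-linked gene Gm773 fell to below background in all 4 KO kidneys, at least 1.70-fold (fitted difference -1.43 ± 0.21). The probe ILMN_1213414, without a gene name, did so at least 1.38-fold (-0.81 ± 0.12). These 9 probes (4 higher, 5 lower, 8 named genes) were the calls of limma among 22856 tested. The adjusted p in limma was 0.0291 for Slc8a1, Ptges and Grin3a, 0.0319 for Tnn, 0.0403 for Gm773, Odf4 and Abhd10, 0.0413 for Antxr1 and 0.0438 for ILMN_1213414. WT and KO kidneys did not overlap in any of the 9, which is no further evidence, since the probes were picked for their small p. Chance gives this in 0.0286 of arrangements for a probe not so picked (exact, two-sided). A further probe of Slc8a1 gave 0.86 ± 0.15, and another was below background in all 4 WT kidneys and detected in 3 KO kidneys (at least 1.06-fold). The further probe of Gm773 was below background in all 4 KO kidneys and detected in 3 of 4 WT kidneys (at least 1.23-fold lower in KO). Further probes gave 0.31 for Antxr1, -0.67 for Odf4 and -0.07 for Abhd10, all detected on every array, and 0.36 for Ptges, detected in 1 of 4 WT and 4 of 4 KO kidneys.

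At an unadjusted p under 0.05 limma had 2947 probes. At an unadjusted p under 0.001 it had 120, where 22.9 would be expected on average with no effect. Probes can vary together between arrays, so a count can lie far above this average without an effect of genotype. Other splits of the arrays, given at the end, did not exclude chance for the 9 calls. With the slide as a block 4 probes passed, namely Slc8a1 (1.13, adjusted p = 0.0413 in limma), Ptges (0.98, 0.0415), Grin3a (-1.07, 0.0413) and, outside the 9, the fatty acid hydroxylase gene Cyp4a12a (1.39, 0.0413). Tnn was then at an adjusted p of 0.0505, Gm773, Odf4 and Abhd10 at 0.0604 and Antxr1 at 0.0639. Within the slides, Slc8a1 differed by 1.34 and 0.91, Ptges by 0.96 and 1.00 and Grin3a by -1.25 and -0.89. Tnn differed by 1.83 and 1.08, Antxr1 by 0.75 and 0.72, Gm773 by -1.48 and -1.38, Odf4 by -0.97 and -0.54 and Abhd10 by -0.89 and -0.61. Without background correction the differences were smaller and the calls ended for Tnn (0.77, adjusted p = 0.0547 in limma), Antxr1 (0.44), Gm773 (-0.76) and Odf4 (-0.47), while Grin3a passed at -0.63 (0.0349). With an offset of 50 the calls of Tnn (0.84, 0.0532), Antxr1 (0.49, 0.0577) and Gm773 (-0.75, 0.0719) ended. Those of Odf4 (-0.63, 0.0944) and Abhd10 (-0.58, 0.164) ended with a median shift per array, and those of Slc8a1 (0.0508), Tnn (0.0937) and Gm773 (0.129) with all probes tested. With only WT and KO arrays in the fit no probe passed (Slc8a1, Ptges and Grin3a at 0.0744, limma). Slide 1 alone had 13 called probes and slide 2 alone 0 (limma). Of the 9 probes 0 passed within a slide. No probe passed without WT 1, WT 2, Het 2 or KO 2, or with the postnatal day in the model. Just 1 passed without WT 4 (Grin3a), 3 without Het 3, 3 without KO 1 (of the 9, 0) and 15 without WT 3 (8 of the 9).

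Genes of the distal convoluted tubule, the segment after the thick ascending limb that fine-tunes magnesium and sodium, rose as a list (camera adjusted p = 8.85e-07, and adjusted p = 0.135 with an estimated correlation). Of its 17 measured members 15 lay higher in KO, with a median difference of 0.37, and 10 rose when adjusted over the list alone (0 over all probes). They included Trpm6, the magnesium channel of this segment (0.73 ± 0.13, from 8.85 to 9.57; further probes 0.75 and 0.43), and Slc8a1 (0.86 ± 0.15 for its brightest probe). Klhl3 (0.36 ± 0.10) and Wnk4 (0.53 ± 0.15) also rose, both regulators of the sodium chloride cotransporter. Slc12a3, that cotransporter and a gene chosen after its values were seen, rose by 0.42 ± 0.15 (adjusted over the list alone), and its 5 probes ranged from 0.38 to 0.78. Of the 17 members 10 are also in other lists, and with the unshared members alone, an alternative chosen after the data were seen, the median was 0.12 and the call ended (camera adjusted p = 0.181). The median was 0.37 with the slide as a block (adjusted p = 9.44e-07) and 0.37 and 0.36 within the slides (adjusted p = 6.22e-05 and 7.66e-06, all camera). These p-values use the preset correlation of 0.01, whereas the estimate for this list was 0.15. Each slide also compares only 2 WT with 2 KO arrays, so the within-slide p-values are no separate replications. With so few arrays, the same holds for the within-slide p-values of the other lists in KO vs WT below. All 4 KO kidneys scored above all 4 WT kidneys (0.34, exact two-sided permutation p = 0.0286, the smallest possible, and 0.200 after adjustment over 28 lists).

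Calcium and magnesium handling genes rose as well: 18 of 25 members lay higher, the median was 0.14, and 7 rose and 1 fell when adjusted over the list alone (0 over all probes). Camera gave adjusted p = 0.00270 for the list, and adjusted p = 0.113 with an estimated correlation. Besides Trpm6 and Slc8a1, the rising members included Cnnm2, which takes part in basolateral magnesium handling (0.41 ± 0.12), and the calcium channels Trpv6 (0.51 ± 0.15) and Trpv5 (0.31 ± 0.11; a further probe -0.11). The calcium pump Atp2b1 (0.47 ± 0.16) rose as well, as did the cation-transporting ATPase Atp13a4 (0.99 ± 0.20), which lies within 20 Mb of Cldn16. Stc2, a stanniocalcin, fell by 0.52 ± 0.16. S100g, a calcium-binding calbindin, differed by 0.54 ± 0.28, and Cldn19, the claudin that pairs with claudin-16, by -0.06 ± 0.10, neither past the threshold. The sign of Cldn19 turned with a median shift per array (0.12) and in slide 2 alone (0.04). With the slide as a block the median was 0.14 (adjusted p = 0.00337) and within the slides 0.20 and 0.07 (0.00266 and 0.0140, camera). This list shares 5 members with the distal convoluted tubule list, among them Slc8a1, Trpm6, Trpv5 and S100g. Of the 25 members 13 are in other lists, and with the unshared ones alone the median was 0.06 and the call ended (camera adjusted p = 0.470). The median of the whole list was 0.07 without KO 4 (0.00373) and 0.08 without background correction (0.00242), with the authors' values (0.00242) and with all probes tested (0.00157, all camera).

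Water handling genes and collecting duct genes also rose. Camera gave adjusted p = 5.02e-06 for water handling (adjusted p = 0.135 with an estimated correlation) and 0.00231 for the collecting duct (adjusted p = 0.405 with an estimated correlation). In the water handling list 15 of 17 members lay higher, with a median of 0.26, and 3 rose when adjusted over the list alone (1 over all probes, Ptges). These were Ptges, the osmolyte transporter Slc6a12 (1.04 ± 0.29) and Aqp2, the vasopressin-regulated water channel (1.02 ± 0.28, from 10.06 to 11.08). In the collecting duct principal cell list 14 of 18 members lay higher, with a median of 0.23, and 4 rose when adjusted over the list alone (0 over all probes): Aqp2, the transcription factors Gata3 (0.60 ± 0.14) and Elf5 (1.21 ± 0.35), and the sodium channel subunit Scnn1g (0.31 ± 0.10). The medians with the slide as a block were 0.26 (adjusted p = 6.60e-06) and 0.23 (0.00270). Within slide 1 the medians were 0.43 and 0.37 (adjusted p = 4.94e-08 and 1.27e-05), and within slide 2, where neither list passed, 0.10 and 0.11 (0.0699 and 0.366, camera). The lists share 4 members, Aqp2, Aqp3, Aqp4 and Avpr2, and the collecting duct list has 4 more in common with sodium handling. With members of no other list, water handling had a median of 0.21 (camera adjusted p = 0.00115), while the collecting duct had 0.10 and its call ended (0.111). The collecting duct median was 0.34 with a median shift per array (0.00112), 0.13 with the mean of all probes per gene (0.00619) and 0.35 without the 3 arrays highest in adipose markers (KO 1, KO 4 and Het 3, left out after the data were seen; 0.00899, all camera). The list scores had an exact two-sided permutation p of 0.0571 each.

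Genes of the renin-angiotensin-aldosterone system and sodium handling rose, with 12 of 14 members higher, a median of 0.19 and 5 that rose when adjusted over the list alone (0 over all probes). Camera gave adjusted p = 0.00422, and adjusted p = 0.274 with an estimated correlation. Sgk1, the aldosterone-induced kinase, rose by 0.75 ± 0.18, and the kinases Wnk4 and Wnk1 (0.43 ± 0.13) and the channel subunit Scnn1g rose with it. The median was 0.19 with the slide as a block (0.00516) and 0.19 and 0.14 within the slides (0.0343 and 0.0489, camera). Of the 14 members 7 are in other lists, Wnk4 and Wnk1 in the distal convoluted tubule list and Scnn1g in the collecting duct list. With the unshared members alone the median was 0.02 and the call ended (camera adjusted p = 0.606), so these values do not show a rise apart from that of the other lists. The call also ended with a median shift per array, at a median of 0.35 (0.0625). The median was 0.08 with all probes tested (0.00967) and 0.09 with the mean of all probes per gene (0.00619, all camera). Fatty acid oxidation and PPAR alpha target genes rose slightly, with 16 of 20 higher and a median of 0.13. That call was close to the threshold (camera adjusted p = 0.0481, and adjusted p = 0.556 with an estimated correlation). Only Cyp4a12a rose when adjusted over that list alone (1.39 ± 0.24; 0 over all probes). With the slide as a block the median was 0.13 (0.0185) and within the slides 0.15 and 0.00177 (0.0812 and 0.0687, camera). The list's call was lost without WT 1 (0.0875), WT 4 (0.202), Het 2 (0.0538), KO 2 (0.197) or KO 3 (0.161). The median was then 0.08 without WT 1, 0.07 without WT 4 and 0.04 without KO 2, against 0.20 without KO 4 (0.00666) and 0.25 without the 3 arrays highest in adipose markers (0.00148). The call also ended with cyclic loess (0.0921), a median shift per array (median 0.22, 0.154), all probes tested (0.0540), the postnatal day (0.0637), day and slide (median 0.05, 0.0975), array weights (0.0884), only the genotypes compared (0.0512), the mean of all probes per gene (0.157) and, its own members unchanged, with the other lists reduced to unshared members (0.111). These 6 lists, all higher, were the ones called among 26, and 0 of them with an estimated correlation.

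**Figure D2:**
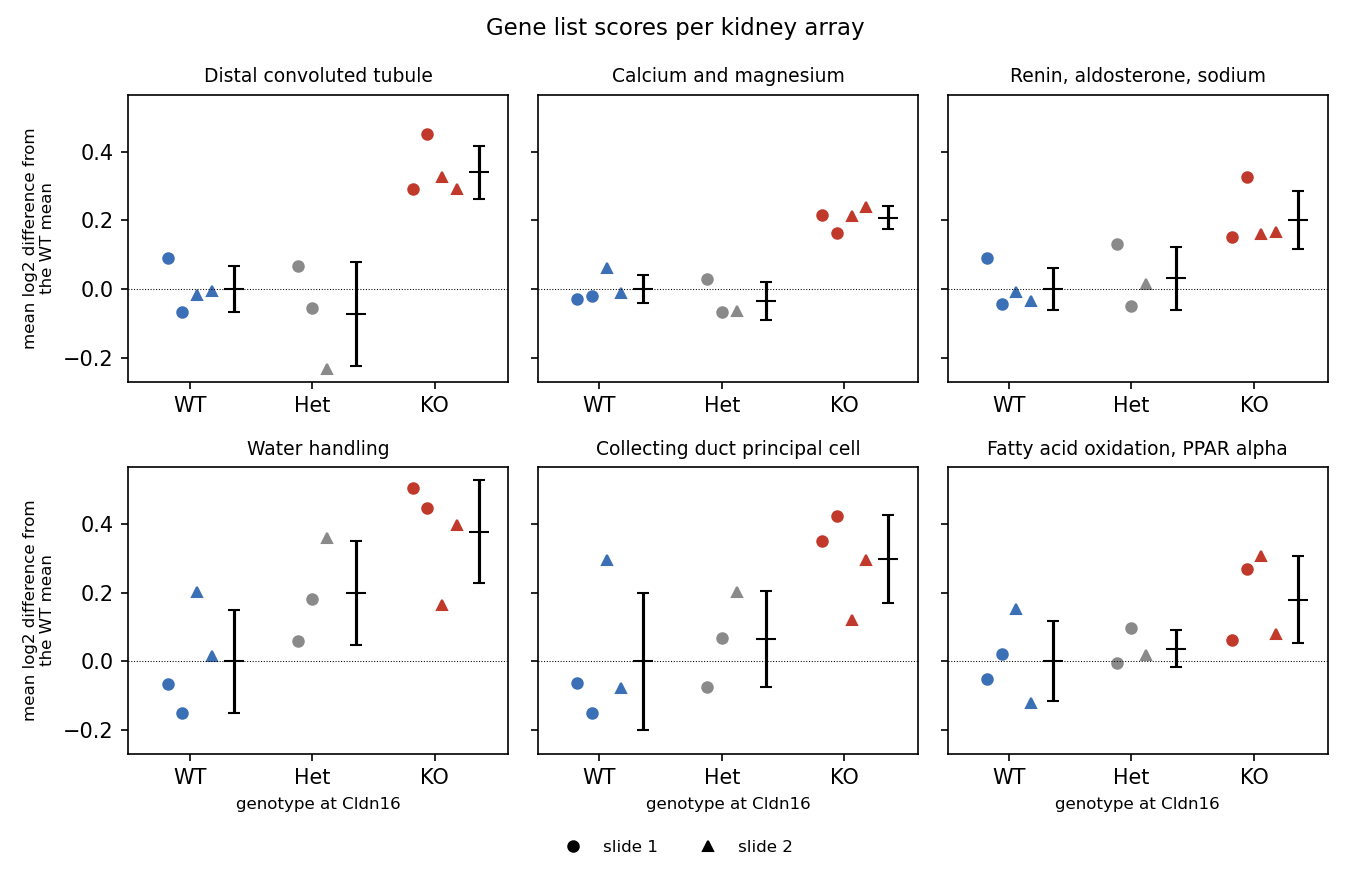
Score of 6 gene lists in each kidney, as the mean log2 difference of the list's genes from the WT mean (vertical axis), by genotype (horizontal axis); circles are arrays of slide 1, triangles of slide 2, and the bars give the mean ± SD of each genotype. Distal convoluted tubule scores were 0.29 to 0.45 in KO and at most 0.09 in WT and Het, while collecting duct scores overlap, since WT 3 had 0.29.

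Several lists tied to the gene's own segment and to hormonal control did not pass in KO vs WT. The thick ascending limb list had 11 of 19 members higher (median 0.01, camera adjusted p = 0.591); adjusted over the list alone 2 rose and 2 fell (0 over all probes), among them the sorting receptor Sorl1 (0.62 ± 0.16) and Ppp1r1b, a phosphatase inhibitor (-0.49 ± 0.11). The claudins and tight junctions list had 13 of 24 higher (median 0.02, camera adjusted p = 0.380) and the vitamin D, PTH and phosphate list 10 of 18 (median 0.04, 0.628). In the last of these Kl, the phosphate and calcium regulator klotho, differed by 0.37 ± 0.13 and the vitamin D receptor Vdr by 0.22 ± 0.15. The vitamin D enzyme genes Cyp27b1 and Cyp24a1 differed by 0.43 ± 0.41 and -0.09 ± 0.36, and none was past the threshold when adjusted over that list alone. Cyp24a1 turned sign under several settings. Proximal tubule (median 0.08, adjusted p = 0.380), podocyte (-0.02, 0.591), thin limb of Henle (0.26, 0.212), endothelium (0.11, 0.146), cholesterol synthesis (-0.04, 0.664), cell cycle (-0.02, 0.781), circadian clock (0.16, 0.212) and muscle and ureter (0.26, 0.502) were not called by camera either. In the intercalated cell list the median (0.05) was opposite in sign to the mean (-0.00170) and to the test (lower, adjusted p = 0.971). In 3 lists the mean was opposite to the median and the test, namely oxidative stress (median -0.04, mean 0.02, lower, 0.987), Cldn16 neighbours (median -0.01, mean 0.04, lower, 0.781) and tubule injury (median 0.13, mean -0.02, higher, 0.971, all camera).

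Adipose tissue markers differed strongly between single kidneys. Their list score was 1.51 in KO 1, 1.44 in Het 3 and 1.25 in KO 4, and at most 0.32 in the other 8 arrays. The list was not called in KO vs WT (8 of 9 members higher, median 0.51, camera adjusted p = 0.0648); Ucp1, the uncoupling protein of brown fat, differed by 1.62 ± 0.57. With those 3 arrays left out, an alternative chosen after the data were seen, 6 lists and 4 probes (0 of the 9) were called in KO vs WT. Slc8a1 then differed by 1.22 (adjusted p = 0.0956 in limma), Ptges by 0.83 (0.136) and Grin3a by -0.99 (0.136), and the distal convoluted tubule median was 0.45 (camera adjusted p = 2.84e-06).

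The mice were of a mixed 129S7/SvEvBrd-Hprtb-m2 and C57BL/6N background. Genes near Cldn16, which are linked to the targeted allele, were compared with the rest. Of the 8 called probes with a mapped gene, 1 (Abhd10) lay within 20 Mb of Cldn16, or 12.5%, against 1.99% of the 19240 tested and mapped probes (two-sided Fisher's exact p = 0.148). Without WT 4, Het 1, Het 3, KO 1 or KO 4 the share was 0% and without WT 3 it was 33.3%. At an unadjusted p under 0.001, a threshold chosen after the data were seen, 10 of 103 probes lay there (9.71%, odds ratio 5.42, 95% interval 2.50 to 10.5, Fisher's exact p = 3.87e-05), 6 of them higher and 4 lower in KO. They included Cd200, a surface glycoprotein that restrains myeloid cells (-1.05), and Timmdc1, an assembly factor of mitochondrial complex I (1.12), named after their values were seen. Fisher's test counts probes as independent, though all come from the same mice and neighbouring genes are inherited together. Its p-values and interval thus leave out the variation between mice.

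**Figure D3:**
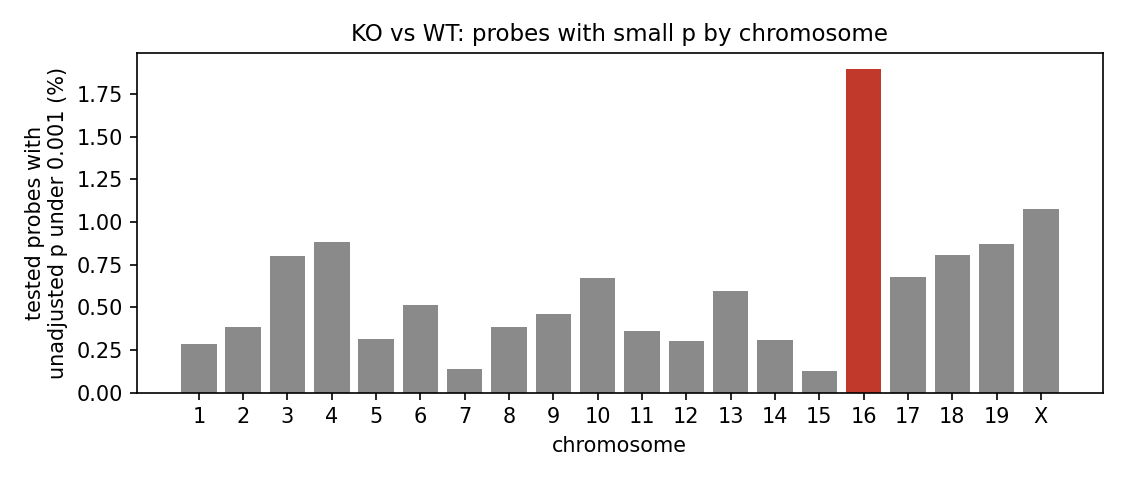
Percentage of the tested probes of each chromosome (vertical axis) with an unadjusted p under 0.001 in KO vs WT, by chromosome (horizontal axis). Chromosome 16, which carries Cldn16, had 1.90% and the X chromosome, with the next highest share, 1.08%.

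Het vs WT asks what the loss of 1 allele does. No single gene passed, and the 5 with the smallest p had ND6, a subunit of mitochondrial complex I, at -0.96 ± 0.15 and Cndp1, a carnosinase, at 0.80 ± 0.13. They were followed by Gm128 (0.74 ± 0.12), the hypoxia-inducible carbonic anhydrase Car9 (1.06 ± 0.19) and Gphn, the scaffold protein gephyrin (0.90 ± 0.17). Car9 and Gphn were detected in 2 and 1 of the 4 WT kidneys. Extracellular matrix genes fell as a list (16 of 21 members lower, median -0.22; Col6a1 -0.50 ± 0.19), as did cell cycle genes (13 of 18 lower, median -0.10; Mcm2 -0.31 ± 0.13). Both lists had adjusted p = 0.531 with an estimated correlation in camera. Water handling genes rose (13 of 17 higher, median 0.20; Slc6a12 0.84 ± 0.31), as did circadian clock genes (9 of 13 higher, median 0.45; Per1 0.70 ± 0.24), again with adjusted p = 0.531 with an estimated correlation. In these 4 lists 0 members passed when adjusted over the list alone and 0 over all probes.

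For single probes limma called 0 in Het vs WT (smallest adjusted p = 0.353; 1543 at an unadjusted p under 0.05). It called 0 with the slide as a block, 1 in slide 1 alone, 8 in slide 2 alone, where the lone Het array is assumed to vary like the other groups, and 1 without WT 3. Camera gave adjusted p = 0.00989 for extracellular matrix, 0.0158 for cell cycle, 0.0182 for water handling and 0.0426 for circadian clock. With the slide as a block the first 3 had medians of -0.23, -0.09 and 0.20 (0.0157 each) and circadian clock 0.45 (0.0645). Within slides 1 and 2 the medians were -0.21 and -0.10 for extracellular matrix (0.00252 and 0.521) and -0.15 and -0.32 for cell cycle (0.181 and 0.00270). They were 0.22 and 0.16 for water handling (0.0262 and 0.0260), and 0.42 and 0.37 for circadian clock (0.147 and 0.0658, camera). Calls depended on single arrays: extracellular matrix on Het 2 (median -0.13, 0.171 without it), cell cycle on WT 4 (0.102) and Het 3 (0.168). Water handling depended on WT 2 (median 0.13, 0.0955) and most on Het 3, without which its median was 0.03 (0.444); Het 3 had a high adipose score (1.44). Its median was also 0.13 without WT 4 and 0.12 without Het 2. The call of circadian clock depended on WT 1 (0.0624), WT 4 (0.113), Het 2 (median 0.28, 0.102), Het 3 (0.187) and KO 2 (0.0530). The cell cycle median was -0.21 without WT 3 and -0.19 without Het 1. With day and slide in the model 0 of the 4 lists passed, at medians of -0.10 for extracellular matrix (0.170), -0.08 for cell cycle (0.0504), 0.11 for water handling (0.0713) and 0.27 for circadian clock (0.112). Without the 3 arrays high in adipose signal 3 lists lost their calls, water handling at a median of 0.03 (0.411), and cell cycle and circadian clock at medians of -0.12 (0.124) and 0.36 (0.166), against -0.10 and 0.45 with all arrays. With a median shift per array, under which the median of all probes lay at 0.10 in Het vs WT, extracellular matrix had -0.10 (0.00124), cell cycle -0.01 (0.00124) and water handling 0.32 (0.00648). With all probes tested the calls of cell cycle (-0.05, 0.0669) and circadian clock (0.24, 0.0675) ended. That of circadian clock ended also with probes detected on all arrays (0.36, 0.0695) and with the mean of all probes per gene (0.25, 0.0851), and cell cycle had -0.16 with array weights (0.0108, all camera). The number of lists called was 2 without WT 4 or Het 3 and 8 without Het 1. Of the lists not called, adipose tissue (median 0.05, mean -0.04, lower by the test) and cholesterol synthesis (median -0.03, mean 0.04, higher) differed in sign between the measures.

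KO vs Het asks what the loss of the remaining allele adds. It uses the same 4 KO arrays as KO vs WT, so a rise found in both is no independent repeat. The distal convoluted tubule list rose here too, with 15 of 17 members higher, a median of 0.41 and 11 that rose when adjusted over the list alone (0 over all probes). These included Slc8a1 (1.17 ± 0.17 for its brightest probe), Trpm6 (0.61 ± 0.14), Kl (0.66 ± 0.14), Klhl3 (0.38 ± 0.11) and Wnk1 (0.45 ± 0.14). Calcium and magnesium handling genes rose too, with 18 of 25 higher, a median of 0.09 and 4 past the list alone (0 over all probes), including Cnnm2 (0.49 ± 0.12). Both lists kept their calls with an estimated correlation: the distal convoluted tubule had a camera adjusted p of 4.30e-12 (adjusted p = 0.0346 with an estimated correlation) and calcium and magnesium handling 5.08e-05 (adjusted p = 0.0230 with an estimated correlation). The size of the second depended on single arrays, since its median was 0.16 without Het 1 (0.000262), 0.18 without Het 3 (8.53e-05), 0.20 without KO 2 (3.07e-06) and 0.14 without KO 4 (0.000108). It was 0.17 without the 3 arrays highest in adipose markers (0.00307), 0.19 with array weights (1.92e-05), 0.06 without background correction (6.16e-05) or with the authors' values (6.14e-05), and 0.05 with all probes tested (0.000175, all camera).

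A further 6 lists were called in KO vs Het with the preset correlation alone. Renin-angiotensin-aldosterone and sodium handling genes rose (12 of 14 higher, median 0.11; camera adjusted p = 0.00457, and adjusted p = 0.359 with an estimated correlation), among them Scnn1g (0.46 ± 0.11). Collecting duct genes rose (15 of 18, 0.16; 0.00427, and adjusted p = 0.383 with an estimated correlation), as did water handling genes (12 of 17, 0.20; 0.00532, and adjusted p = 0.383 with an estimated correlation), with Ptges at 0.69 ± 0.14. Adipose tissue genes rose (9 of 9, 0.46; 0.00457, and adjusted p = 0.494 with an estimated correlation), as did cell cycle genes (16 of 18, 0.12; 0.0104, and adjusted p = 0.383 with an estimated correlation). Podocyte genes fell (8 of 10 lower, median -0.16; 0.0432, and adjusted p = 0.383 with an estimated correlation), with Thsd7a at -0.27 ± 0.12. Adjusted over the list alone, 3, 1, 1, 0, 0 and 0 members passed in these 6 lists, and 0 over all probes. Single arrays decided several calls and sizes. Without Het 1 the adipose median was 0.28 (0.285), while it was 1.53 without Het 3 (6.77e-10), 0.90 without KO 2 (5.26e-05) and 0.79 without KO 3 (0.000379). The adipose call also ended without Het 2 (0.166), KO 1 (0.151) or KO 4 (0.0646). The collecting duct call ended without Het 1 (0.119), and that of water handling without Het 1 (median 0.10, 0.200) or KO 1 (0.0550). Cell cycle lost its call without Het 3 (0.109) or KO 3 (0.0511) and had a median of 0.21 without Het 1 (0.00654). For podocytes the median was -0.06 without Het 2 (0.585) and -0.25 without Het 1 (0.00787), and the call ended also without Het 3 (0.0611), KO 1 (0.123) or KO 4 (0.131). The median of renin-angiotensin-aldosterone and sodium handling was 0.19 without Het 1 (0.00342) and 0.07 without Het 2 (0.0411). It was 0.05 with all probes tested (0.0237), and the call ended with a median shift per array (0.09, 0.0507). With all probes tested the cell cycle call ended (0.09, 0.0582), and with the mean of all probes per gene those of water handling (0.13, 0.0529) and podocytes (-0.11, 0.209) did. Podocytes lost their call with a median shift too (-0.15, 0.0762), and the adipose median was 1.06 with array weights (3.54e-05, all camera).

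Slide 2 held 1 Het array, Het 3, so its p-values below assume that this array varies like the other groups, and they are no replication of slide 1. Within slides 1 and 2 the KO minus Het medians were 0.27 and 0.56 for the distal convoluted tubule (7.57e-07 and 2.18e-08; 0.45 with the slide as a block, 3.59e-12) and 0.16 and 0.05 for calcium and magnesium handling (0.000462 and 0.0128; 0.12 as a block, 9.56e-05, all camera). They were 0.26 and -0.04 for the collecting duct (5.97e-06 and 0.626; block 0.17, 0.00719) and 0.19 and 0.13 for renin-angiotensin-aldosterone and sodium handling (0.00947 and 0.136; block 0.11, 0.00627). They were 0.27 and 0.01 for water handling (7.03e-06 and 0.549, lower by the test in slide 2; block 0.18, 0.0134) and 1.52 and -0.76 for adipose tissue (1.66e-08 and 0.0128; block 0.45, 0.0134). The last 2 lists had 0.02 and 0.31 for cell cycle (0.494 and 0.000312; block 0.11, 0.0141) and -0.19 and -0.14 for podocytes (0.0932 and 0.301; block -0.19, 0.0350, all camera). With members of no other list, the distal convoluted tubule had a median of 0.38 (0.0198) and kept its call, while calcium and magnesium handling (0.05, 0.0696), renin-angiotensin-aldosterone and sodium handling (0.02, 0.623), the collecting duct (0.16, 0.0724), water handling (0.14, 0.0724) and podocytes (-0.16, 0.0665, all camera) lost theirs. The adipose score was high in KO 1, KO 4 and Het 3, as given above for KO vs WT. Without these arrays cell cycle and podocytes lost their calls, cell cycle at a median of 0.12 (0.0642), as with all arrays, and podocytes at -0.11 (0.340), while the collecting duct had 0.28 (0.00307, all camera). Of the lists not called, endothelium (median -0.01, mean 0.01, lower by the test) and thin limb (median -0.02, mean 0.03, higher) differed in sign between the measures.

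Among single probes limma called 0 in KO vs Het (smallest adjusted p = 0.0944; 1243 at an unadjusted p under 0.05). Slc8a1 had 1.16 ± 0.16 (adjusted p = 0.0944), Rdh12, a retinol dehydrogenase detected in 1 of 3 Het kidneys, 0.70 ± 0.11 and Grin3a -0.92 ± 0.14, followed by Cmss1 (-1.25 ± 0.23, chromosome 16) and the progenitor transcription factor Sox9 (0.90 ± 0.17). With the slide as a block 0 were called, in slide 1 alone 6, in slide 2 alone, with its lone Het array, 8 and without WT 4 1 (Grin3a, adjusted p = 0.0230 in limma).

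The design also allows a test of whether heterozygotes lie midway between the homozygotes. Of the 9 probes called in KO vs WT, 6 were detected in both homozygotes, and for 5 of these the Het mean was nearer to WT than to KO. For Slc8a1 it lay at -0.03 of the way from WT to KO, for Grin3a at 0.13, for Odf4 at 0.23, for Abhd10 at 0.28 and for Ptges at 0.30, whereas Antxr1 lay at 0.61. For the other 3, Tnn, Gm773 and ILMN_1213414, 1 homozygote was below background, so their position is not known. The called probes do not stand for all probes with small p. At an unadjusted p under 0.01 in KO vs WT, the median position was 0.465 for 33 probes within 20 Mb of Cldn16. It was 0.522 for the mapped probes elsewhere, so both medians lay about halfway. Probes picked by chance would centre there too, because WT and KO had 4 arrays each. The medians thus do not tell a halfway effect from noise. Limma called 0 probes as departing from the midpoint over all tested probes (smallest adjusted p = 0.999, with 954 at an unadjusted p under 0.05). It called 1 in slide 1 alone and 0 with the slide as a block. Slide 2 alone has 1 Het array. Among the 9 probes, Slc8a1 departed by -0.60 (unadjusted p = 0.000931 in limma) and Grin3a by 0.39 (0.00915). The next smallest unadjusted p among them was 0.0713 for Odf4.

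Between the slides, with genotype in the model, limma called 0 probes (smallest adjusted p = 0.221; 1580 at an unadjusted p under 0.05) and 1 without WT 3 or without Het 3. Between postnatal days 59 and 58 it called 1 probe, of the asparagine synthetase gene Asns, named after its value was seen (0.94, adjusted p = 0.00544; 1441 at an unadjusted p under 0.05).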

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

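The values below are single kidneys that lay far from the other 3 of their genotype, and no test was chosen for them after they were seen. The measure is the gap to the nearest of the others divided by the range of the group and it was set against Dixon's 95% critical value for 4 samples. Of 180 groups of 4 examined 12 stood out, where chance at 1 in 20 gives 9, and groups of 3 (Het) were not examined. No explanation was tested for them.

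WT 3 accounted for 6 of the 12. It lay apart on the 1st principal component (-3.01, against -19.1 to -18.4 in the other WT kidneys; gap 0.953 of the range) and on the 2nd (-32.1, against -3.40 to 0.0259; 0.893). Its log2 intensity of the collecting duct transcription factors was high, with 8.28 for Elf5 against 6.75 to 7.02 (gap 0.82902) and 8.93 for Gata3 against 8.55 to 8.59 (0.888). Its Cnnm2 intensity was low (10.26, against 10.59 to 10.60; 0.974), and its intensity of Cd52, a lymphocyte surface antigen, was 9.09 against 9.01 to 9.02 (0.887), a small difference in a tight group.

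KO 2 accounted for 4. Its score of the renin-angiotensin-aldosterone and sodium handling list was 0.33 against 0.15 to 0.17 in the other KO kidneys (gap 0.910 of the range), and its circadian clock score was 0.25 against 0.12 to 0.14 (0.853). Its Wnk1 intensity was 12.74 against 12.26 to 12.31 (0.898), and its Gm128 intensity 5.61 against 5.93 to 5.96 (0.918). Grin3a in WT 4 was 6.13 against 6.68 to 6.73 in the other WT kidneys (0.903), which is still above the KO mean of 5.50. Cldn11, a claudin of myelin and Sertoli cells, was 6.63 in KO 3 against 9.51 to 9.87 in the other KO kidneys (0.888).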

How the results depend on the processing

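Chosen after the data were seen were the omission of the 3 arrays with the most adipose signal, the lists without shared members and the unadjusted p under 0.001 near Cldn16; the other alternatives were fixed in advance. In KO vs WT the 8 called genes kept their direction in all 214 values and their call in 81, and the 6 called lists kept their direction in all 180 values and their call in 151. The kept direction of the genes is no further evidence. WT and KO kidneys did not overlap in them, so leaving out arrays could not turn it. Of 995 values of the genes not past the threshold 978 stayed so, 8 passed and 9 turned sign. In Het vs WT all 348 gene values and 90 of 120 list values stayed as reported, with 30 list calls lost. In KO vs Het 373 of 377 gene values and 201 of 239 list values did, with 4 genes gained, 35 list calls lost and 3 list values reversed. Signal over background limits the dim genes (Tnn, Gm773, ILMN_1213414, Car9, Gphn), and the adipose list had too few genes for a value over probes detected on all arrays. The cause of the changes below was not tested, except where fewer arrays or genes entered.

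The number of probes called in KO vs WT went from 9 to 4 with the slide as a block (3 shared), 0 with the postnatal day, 0 with day and slide, 0 in slide 2 alone, 14 with array weights (9 shared), 20 with a trended and robust prior (9 shared), 0 with only the 2 genotypes in the fit, 4 without the 3 adipose-rich arrays, and 0 to 15 without 1 array. The split of 4 higher and 5 lower became 10 and 3 (6 of 13 shared) with a median shift per array, under which the median of all probes lay at 0.106 log2 units in KO vs WT. It was 4 and 2 with no background correction or the authors' values (4 shared each) and 4 and 3 with an offset of 50 (5 shared). Called lists went from 6 to 0 with an estimated correlation, to 1 with members in no other list (water handling, camera adjusted p = 0.00115) and to 5 to 9 without 1 array. Their adjusted p in camera ranged over the alternatives from 1.60e-07 to 0.181 for the distal convoluted tubule, 4.94e-08 to 0.135 for water handling, 1.27e-05 to 0.405 for the collecting duct, 0.000854 to 0.470 for calcium and magnesium, 0.00199 to 0.606 for renin-angiotensin-aldosterone and 0.00148 to 0.556 for fatty acid oxidation. The share of called probes near Cldn16 (12.5%) was 0% within 10 Mb and with the slide as a block, 9.71% at an unadjusted p under 0.001, 15.4% with a median shift, 23.1% with array weights and 0% to 33.3% without 1 array.

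Slide 2 held 1 Het array. In Het vs WT the 0 called probes became 1 in slide 1 alone, 8 in slide 2 alone and 0 to 1 without 1 array, and the number of called lists went from 4 to 7 with a median shift (4 of them shared), 2 with all probes (2 shared), 0 with day and slide, 7 in slide 2 alone (2 shared), 0 with an estimated correlation, 2 without the adipose-rich arrays (1 shared) and 2 to 8 without 1 array. In KO vs Het the 0 called probes became 2 with no background correction, 2 with the authors' values, 6 in slide 1, 8 in slide 2, 2 with the trended prior and 0 to 1 without 1 array, and the number of called lists went from 8 to 2 with an estimated correlation (2 shared), 4 with members in no other list (3 shared, and claudins and tight junctions) and 7 to 10 without 1 array. The 0 probes off the midpoint became 1 in slide 1 and 11 in slide 2. The 0 probes between slides became 1 with a median shift, 1 with the postnatal day and 0 to 1 without 1 array.

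Values that turned sign in KO vs WT were Cldn19 (0.12 with a median shift, 0.041 in slide 2), Cyp27b1 (-0.025 without the adipose-rich arrays) and Cyp24a1 (0.050 with a median shift, 0.050 in slide 2, 0.033 with array weights, -0.43 to 0.15 without 1 array). In KO vs Het within slide 2 the medians of adipose tissue (-0.76) and the collecting duct (-0.044) turned sign, as did the test of water handling (median 0.00825).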

Other observations

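Chosen only after the result was seen were the comparisons with cortex, with Slc12a3 and with the thin limb, and the unadjusted p under 0.001 around Cldn16. Immune and stress genes, outside the comparisons described so far, moved in both directions. Of 20 immune cell genes 6 were higher and 14 lower in KO than in WT (median -0.15, camera adjusted p = 0.165); adjusted over the list alone 3 rose and 4 fell (0 over all probes). Cd52, a lymphocyte surface antigen, fell by 1.00 ± 0.17 (SE), from 9.04 in WT (n = 4) over 8.47 in Het (n = 3) to 8.03 in KO (n = 4), and the T cell receptor component Cd3d fell by 0.55 ± 0.11, while H2-Ab1, a class II antigen presentation gene, rose by 0.78 ± 0.23. In Het vs WT 4 immune genes fell when adjusted over the list alone (0 over all probes), among them Cd52 (-0.57 ± 0.19) and Cd3d (-0.41 ± 0.12), with the list at camera adjusted p = 0.0515.

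Interferon response genes had 15 of 20 members lower in KO than in WT (median -0.11, camera adjusted p = 0.0702). All 4 KO scores lay below all 4 WT scores (exact two-sided permutation p = 0.0286, the smallest possible, and 0.200 after adjustment over 28 lists). As for the distal convoluted tubule list, that adjusted value decides nothing. Extracellular matrix genes had 16 of 21 lower (median -0.09, camera adjusted p = 0.146). Among tubule injury genes Lcn2, an iron-binding lipocalin (-0.87 ± 0.25), and Timp1, a metalloproteinase inhibitor (-0.57 ± 0.17), fell when adjusted over the list alone (0 over all probes). In the immediate early and heat shock list (median 0.12, adjusted p = 0.165) the heat shock gene Hspa1a rose by 0.85 ± 0.23 and Jun fell by 0.48 ± 0.13, adjusted over the list alone (0 over all probes). Tie1, an endothelial receptor, rose by 0.44 ± 0.11 in KO and by 0.48 ± 0.11 in Het against WT, adjusted over the endothelium list alone (0 over all probes). Cldn11 differed by 1.74 ± 0.76 in KO vs WT and did not pass within the claudin list. Blood and adrenal gland genes, too few for camera, had score differences of -0.41 (exact permutation p = 0.286) and 0.30 (exact permutation p = 0.0571).

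A 1st pattern is the rise of the distal convoluted tubule list in KO kidneys. A larger share of cortex in the KO pieces would raise proximal tubule and podocyte genes as much. Their scores differed by 0.06 and -0.03 in KO against WT, where the list differed by 0.34. This argues against cortex as the whole source. The list score exceeded their mean by 0.32 (exact permutation p = 0.0286, the smallest possible). The list was picked for its rise, so that p is no further evidence. A larger share of distal convoluted tubule cells would raise the other 16 members less than Slc12a3, the cotransporter restricted to these cells. Their score minus Slc12a3 differed by -0.19 (exact permutation p = 0.200), which leaves this share open. That value sets unlike probe choices side by side. The members entered by their brightest probe, and Slc12a3 by the mean of its probes with a mean log2 intensity above 7. By its brightest probe alone Slc12a3 rose by 0.42. Slc8a1 by itself exceeded Slc12a3 by 0.47 (exact permutation p = 0.0286; probes with a mean log2 intensity above 7), but as the list's top gene, picked for its rise, it excludes nothing for the list. A slide difference is argued against by the design, since each slide held 2 WT and 2 KO and a shift common to a slide cancels. The shifts within the slides add little to this, the smaller being 0.321 (SD within genotype and slide 0.0813). More of these cells and more transcript per cell, as a response to the lost allele, both stay open as candidate explanations.

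A 2nd pattern is the rise of water handling and collecting duct genes. A larger share of medulla in the KO pieces could give it, and thin limb genes in neither list differed by 0.09 (5 genes, exact permutation p = 0.514), which leaves this open, since 5 genes are few. The slides as the source are argued against by the design, since each slide held 2 WT and 2 KO and a shift common to a slide cancels. The shifts within the slides were 0.138 and 0.490 (SD within genotype and slide 0.117). With 2 arrays against 2 the smaller is hardly beyond its spread, and neither list passed camera in slide 2. The rise is thus not shown in slide 2 by itself. A response of the collecting duct to the genotype stays open as well.

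A 3rd pattern is the excess of small p-values around Cldn16. Chance clustering along the chromosomes is made less likely but is not excluded. Of 123 windows of 40 Mb elsewhere, 1.63% held a share as high as the 2.62% around the gene, the highest being 4.17% on the X chromosome. The windows with such a share overlapped on the X chromosome and held the called gene Gm773. In mice of mixed background, strain DNA may differ between the groups elsewhere too, so the windows are no pure measure of chance. The windows step by 20 Mb, so neighbours overlap and are not independent. The threshold was chosen after the data were seen, and the planned test gave a Fisher's exact p of 0.148. DNA of the 129S7/SvEvBrd-Hprtb-m2 strain linked to the targeted allele may be the source: it predicts heterozygotes about halfway between the homozygotes. Their median position on the log2 scale over 33 probes was 0.465 (bootstrap 95% interval 0.308 to 0.572). The interval resamples probes, which come from the same mice, so it leaves out the variation between mice. By this position linked DNA cannot be told apart from an effect of the lost gene, since probes elsewhere had a median of 0.522. Nor can it be told apart from noise, since probes picked by chance also centre halfway when WT and KO have equally many arrays.

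Other splits of the same arrays into groups of the same sizes show whether chance can be excluded, and it could not be for the counts above 0. The splits exchanged arrays freely across the slides, in the model without the slide. For KO vs WT 2 of 35 splits gave at least the 9 probes observed, and the highest other count, 17, came from exchanging WT 3 and KO 3. For lists, 6 of 35 splits gave at least the 6 of KO vs WT (highest other 9), 11 of 35 the 4 of Het vs WT (highest other 11) and 4 of 35 the 8 of KO vs Het (highest other 9). Where the real count is 0 every split reaches it by construction, so the splits decide nothing there: 35 of 35 for Het vs WT (highest other 3), 35 of 35 for KO vs Het (highest other 24), 100 of 100 drawn for the midpoint (highest other 39) and 100 of 100 for the slides (highest other 8). The splits with 24 and 39 probes, and midpoint splits with 25 and 20, point to a structure of the samples: each sets Het 3, KO 1 and KO 4 apart as 1 group, the 3 arrays with the highest adipose scores (1.44, 1.51 and 1.25).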
